A study of Sus scrofa with 12 samples.

How the data were processed

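Hypothalamus RNA from 12 pigs (Sus scrofa), all 140 days old, was measured on 12 Affymetrix Snowball arrays, a whole-transcript pig array, with 1 array per pig. The labels placed 6 pigs in the high feed efficiency group and 6 in the low feed efficiency group, and each group held 3 males and 3 females. Total RNA was extracted with a phenol reagent, treated with DNase and column-purified, then transcribed to DNA, fragmented and labelled with biotin, per the labels. Each array was taken as 1 pig because the labels give each its own pig identifier. Whether the males were castrated, the time of day of sampling, the litter and the array batch are not given in the sources used here.

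The values used were the deposited series table, 1 value per probe set and array. They were taken as log2 values because they ran from near 0 to below 16 and the array medians lay between 4.35 and 4.42, so the log2 scale of the values deposited by the authors was read from their range and not from a statement. GCOS version 1.1.1 is the 1 tool that the submitters' processing notes name. The background correction, summary method and normalization between arrays are not given in the sources used here, so every fold below assumes a log2 scale. No column of the table was left out.

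The table held 47845 rows. The 123 control rows were left out, and of the remaining 47722 probe sets the 25 percent with the lowest mean over all arrays were left out too, which set the limit at a mean of 2.43 and left 35791 probe sets in the tests. The 69 background probe sets, which serve to measure background, had means from 1.30 to 7.49 that were higher in probe sets richer in G and C, so a dim signal can lie at background. Gene names came from the platform annotation: 26426 rows had 1 symbol, 0 had several and 21419 had none, and 13394 of the 13755 symbols were current RefSeq symbols. For list genes, 5 older symbols were updated through RefSeq synonyms. Some symbols were carried by so many probe sets that the match is doubtful: LOC396781 by 251, RPL19 by 74, RTN2 by 53 and GNAS by 20. Rows without a symbol are unnamed here.

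Each comparison was fitted with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, without trend or robust settings), with Benjamini-Hochberg adjustment over the 35791 probe sets and a threshold of 0.05. Feed efficiency was tested with sex as a term and sex with feed efficiency as a term. The interaction of both, and the feed efficiency difference within males and within females, came from a fit of the 4 groups of feed efficiency and sex. Differences are low minus high feed efficiency or female minus male, with limma's standard error (SE), and intervals are 95 percent. The share of variance between the feed efficiency groups was tested by exact permutation within sex.

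Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. A gene was represented by its brightest tested probe set, which gave 12609 genes. Of 38 lists, 21 of gene functions and 17 of cell type markers, 37 had at least 4 tested genes; the Y-linked list did not. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. For feed efficiency the rule named, per direction, the 12 genes past the threshold with the largest difference, filled up with the smallest unadjusted p; 16 appetite and hormone genes whatever their values; and of each list up to 4 members with the smallest unadjusted p. For sex it named 8 genes per direction, the Y-linked genes and XIST, and for the interaction and each sex 5 genes per direction. Other genes are said to have been chosen after their values were seen.

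The fits were tested on simulated data with the real means and spreads of the 35791 probe sets and noise independent between them. Each simulation held 100 probe sets changed by 1 and 100 changed by 0.5 at once, so the shares called hold for that setting only. Of 100 probe sets changed by 1 on the log2 scale, 74 percent were called for feed efficiency, 71 percent for sex, 17 percent for the interaction, 39 percent within males and 46 percent within females; at a change of 0.5, the shares were 30, 33, 0, 2 and 2 percent. The number of arrays limits the precision.

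Alternatives were no filter on dim probe sets, a filter on the dimmest 50 percent, another quantile normalization, equal array medians, eBayes with trend and robust settings, array weights, averaging a gene's probe sets, a looser threshold of 0.1, unmoderated linear models, other covariates, scaling to unit variance for the share of variance, and leaving out each pig in turn. Correlations between arrays, all below 0.975, showed no pair of duplicates. Plots were drawn with matplotlib version 3.10.9.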

Results

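Gene expression was profiled in the hypothalamus, the brain region that controls feeding, energy balance and pituitary hormone release, of pigs that differed in feed efficiency, the efficiency with which an animal turns feed into growth. There were 6 pigs in the high feed efficiency group and 6 in the low group, with 3 males and 3 females in each, and all were 140 days old. Array medians lay between 4.35 and 4.42 on the log2 scale, and each array's mean correlation with the others lay between 0.966 and 0.972. The 1st principal component held 12.9% of the variance. The question was which hypothalamic transcripts differ between pigs of high and low feed efficiency.

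Most of the neuropeptide and receptor genes that govern appetite had nearly the same array signal in both groups, with LEPR, GHRH and MC4R furthest apart. AGRP, which encodes the appetite-stimulating agouti-related peptide, had a log2 signal of 4.69 ± 0.26 (SD, n = 6) in the high group and 4.61 ± 0.32 (SD, n = 6) in the low group. NPY, the gene of the appetite-stimulating neuropeptide Y, stood at 4.98 ± 0.37 and 5.09 ± 0.38 (SD, n = 6 each). CARTPT, whose peptide reduces feeding, stood at 9.20 ± 0.43 and 9.20 ± 0.12 (SD, n = 6 each), and PMCH, the precursor of melanin-concentrating hormone, at 8.04 ± 0.42 and 8.03 ± 0.29 (SD, n = 6 each). HCRT, which encodes the wake- and feeding-promoting orexins, was measured at 8.35 ± 0.17 in the high and 8.22 ± 0.25 in the low group (SD, n = 6 each). The largest differences among the fixed genes were those of the leptin receptor gene LEPR, -0.42 ± 0.40 (SE), of the growth hormone-releasing hormone gene GHRH, 0.28 ± 0.33 (SE), and of the melanocortin receptor gene MC4R, 0.24 ± 0.13 (SE). MC4R did not overlap between the groups in males, at 4.34 to 4.71 in high and 4.94 to 5.16 in low males. In females it overlapped, at 5.03 to 5.29 in the high and 4.95 to 5.21 in the low group. This split by sex was looked at after the values were seen. Single pigs moved the values of several of these genes. The NPY difference of 0.11 was 0.20 without high feed efficiency replicate 5 and 0.04 without high feed efficiency replicate 6. That of PMCH was 0.00 with all pigs and -0.16 without high feed efficiency replicate 6. The LEPR difference was -0.07 without low feed efficiency replicate 3 and -0.67 without high feed efficiency replicate 6. The other probe sets of LEPR averaged 0.10. The GHRH difference ranged from 0.11 to 0.52 without single pigs, with 0.52 without high feed efficiency replicate 5 and 0.11 without high feed efficiency replicate 2. The differences of SST, TRH, OXT and AVP, which encode somatostatin, thyrotropin-releasing hormone, oxytocin and vasopressin, were -0.10 ± 0.12, -0.08 ± 0.09, -0.07 ± 0.17 and 0.13 ± 0.14 (SE). Those of CRH, GHSR and INSR, the genes of corticotropin-releasing hormone and of the ghrelin and insulin receptors, were 0.01 ± 0.15, 0.02 ± 0.10 and 0.04 ± 0.08 (SE). None of these 15 genes passed the limma test, and the lowest adjusted p among them was 0.814. For 13 of the 15, all but LEPR and GHRH, the 95% interval of the difference over both sexes excluded a 1.5-fold change in array signal. Of these 13, AGRP, NPY, MC4R, GHSR, CRH and INSR had mean signals within the background probe sets' range, 1.30 to 7.49. A signal there can lie at background, depending on the G and C content of its probes. For these genes the interval therefore does not exclude a 1.5-fold change in transcript. POMC, the precursor of the satiety peptide α-MSH, was named by no probe set in the annotation used here.

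**Figure D1:**
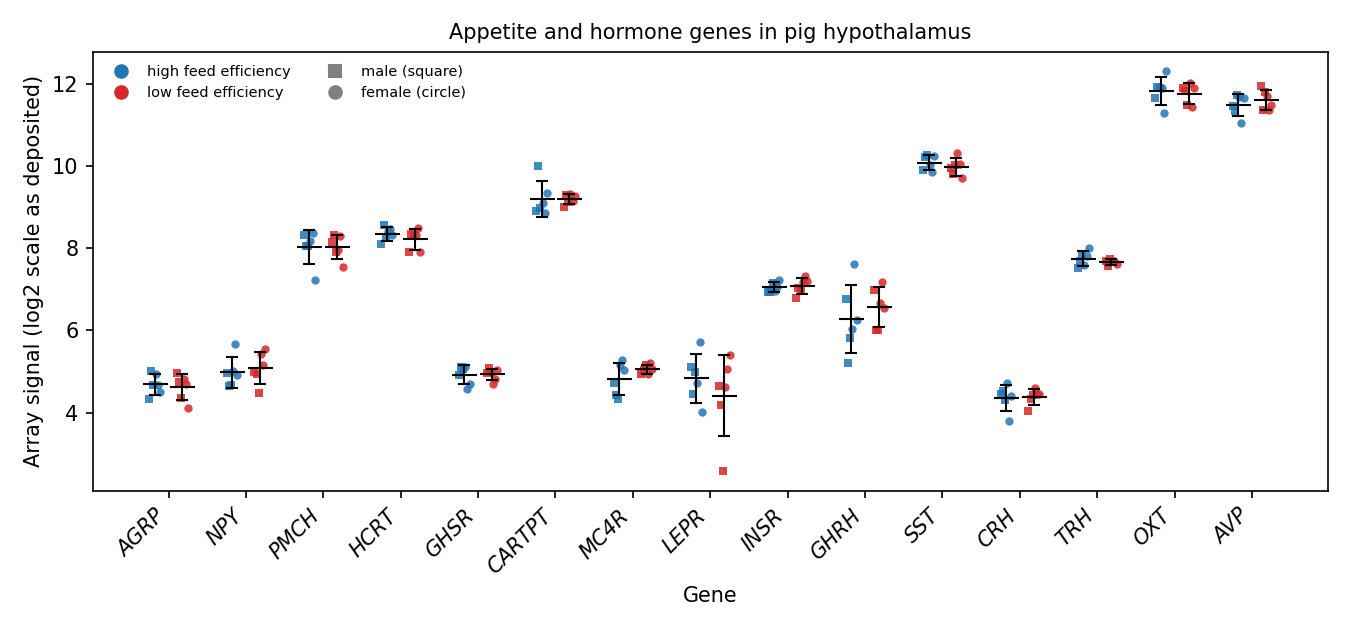
Log2 array signal (y axis) of 15 appetite and hormone genes (x axis) in each of the 12 pigs, with squares for males, circles for females, blue for high and red for low feed efficiency; black bars give the mean and SD of 6 pigs. The groups overlapped for every gene shown, from AGRP at 4.69 and 4.61 to OXT at 11.84 and 11.77.

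Over the 35791 probe sets tested, limma called 0 as different between low and high feed efficiency at an adjusted p under 0.05, and the smallest adjusted p was 0.714. At an unadjusted p under 0.05 there were 2201 probe sets, 1069 higher and 1132 lower in the low group, against 1790 expected by chance. Because probe sets can vary together, this count alone shows no excess. The split by feed efficiency held 10.9% of the variance after sex means were removed, against a median of 9.86% over reassignments of the pigs. It did not stand out from them (exact permutation p = 0.105, 42 of 400 reassignments as large). These reassignments kept sex but ignored a possible pairing of same-numbered pigs, which is described with the processing below. Without high feed efficiency replicate 6 the share was 13.01% (exact permutation p = 0.02, against 0.065 to 0.315 without any other pig), and without low feed efficiency replicate 2, 1 probe set passed (adjusted p = 0.0328).

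The genes of smallest unadjusted p, none of which passed, were led by TEAD3, a transcription factor of the Hippo pathway. Its signal was 4.37 ± 0.26 in the high and 3.64 ± 0.14 in the low group (SD, n = 6 each), a difference of -0.74 ± 0.11 (SE), and its other probe set differed in the same direction, by -0.52. ARRDC1, an arrestin-domain gene, differed by -0.47 ± 0.08 (SE), LHCGR, the receptor of luteinizing hormone, by -0.75 ± 0.15 (SE), PTBP1, a splicing repressor, by -0.66 ± 0.13 (SE) and the ribosomal protein gene RPL18 by -0.72 ± 0.15 (SE). ECHDC3, AKR1E2, KIFC3, LOC396781, MCTS1, DNASE1L1 and FOXP4 made up the rest of this direction, with KIFC3, a kinesin, at -2.31 ± 0.45 (SE) and a low-group signal of 1.60, within the range of the background probe sets. On the other side, NDUFAF4, an assembly factor of respiratory complex I, stood at 4.19 ± 0.12 in the high and 4.59 ± 0.08 in the low group (SD, n = 6 each), a difference of 0.40 ± 0.08 (SE). XPO1, a nuclear export receptor, differed by 0.42 ± 0.09 (SE), the cohesin subunit STAG2 by 0.48 ± 0.11 (SE), the lymphatic growth factor gene VEGFC by 0.88 ± 0.19 (SE), and DENND1A by 0.45 ± 0.09 (SE). GATAD2B, RTN2, ESF1, RBM34, SFTPC, THRAP3 and FAT4 completed this direction. Of these 24 genes, 18 had another tested probe set, and for 10 of the 18 the other probe sets moved on average the same way.

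No fixed gene list passed the camera test for feed efficiency, with 0 of 37 lists called and a lowest adjusted p of 0.317, shared by 5 lists (0.886 with an estimated correlation). Among the circadian clock genes, 10 of 16 were lower in the low group, by -0.08 on average, and by -0.03 with no filter on dim probe sets (adjusted p = 0.521). DBP, a transcription factor driven directly by the clock, stood at 7.27 ± 0.11 in the high and 6.84 ± 0.23 in the low group (SD, n = 6 each), a difference of -0.42 ± 0.11 (SE), and all 6 low pigs lay below the high group's mean. NR1D1, the clock repressor REV-ERBα, differed by -0.38 ± 0.11 (SE), again with all 6 low pigs on that side. For both genes the groups overlapped. DBP was 7.08 in high and 7.19 in low feed efficiency replicate 1, and NR1D1 was 7.01 in high replicate 4 and 7.18 in low replicate 5. Both passed limma adjusted over the list alone, with adjusted p = 0.0344 and 0.0391, and 0 of the 16 passed over all probe sets. BHLHE40 and PER3, further clock-controlled genes, differed by -0.21 ± 0.09 and -0.30 ± 0.14 (SE).

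**Figure D2:**
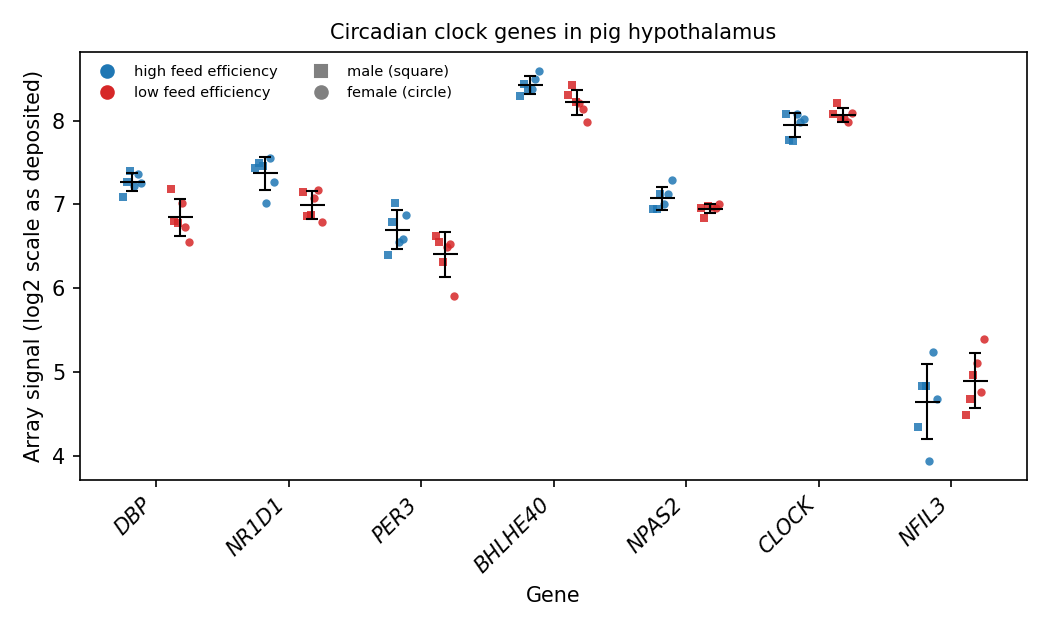
Log2 array signal (y axis) of 7 circadian clock genes (x axis) in each of the 12 pigs, with squares for males, circles for females, blue for high and red for low feed efficiency; black bars give the mean and SD of 6 pigs. DBP lay at 7.27 in the high and 6.84 in the low group, CLOCK and NFIL3 differed by 0.12 and 0.25, and NPAS2 by -0.12.

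Interferon-induced genes were on average 0.08 higher in the low group, with 17 of 25 positive. IFIT5 differed by 0.29 ± 0.08 (SE), IFIH1 by 0.27 ± 0.12, IFIT3 by 0.24 ± 0.13 and DDX60 by -0.68 ± 0.31. Glucocorticoid-responsive genes were 0.13 higher, with 11 of 16 positive, and 0.07 higher with a gene's probe sets averaged. Members were the metallothionein gene MT1A at 0.42 ± 0.18 (SE), MAOA at 0.20 ± 0.10 and SULT1A1 at 0.26 ± 0.13. The mineralocorticoid receptor gene NR3C2 differed by -0.19 ± 0.07. Meningeal fibroblast markers were 0.13 higher, with 10 of 12 positive, such as the collagen-binding proteoglycan LUM at 0.29 ± 0.11 (SE), COL3A1 at 0.22 ± 0.14, COL1A1 at 0.51 ± 0.34 and PTGDS at -0.14 ± 0.10. Chaperones were 0.04 higher, with 16 of 24 positive. DNAJC3 and PDIA4, which act in the endoplasmic reticulum, differed by 0.17 ± 0.07 and 0.17 ± 0.08 (SE), HSPA5 by 0.12 ± 0.07 and HSPB1 by -0.13 ± 0.07. None of these members passed. Single pigs decided whether the first 3 of these lists were called. The interferon list passed without high feed efficiency replicate 4 (mean 0.13, adjusted p = 0.00394, up to 0.897 under the other alternatives), the glucocorticoid list without low feed efficiency replicate 4 (adjusted p = 0.0109, otherwise up to 0.886) and the meningeal list without high feed efficiency replicate 1 (mean 0.20, adjusted p = 0.0169, otherwise up to 0.886). The interferon mean was 0.04 without low feed efficiency replicate 2 and 0.04 without low feed efficiency replicate 6.

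In the remaining functional lists, means lay close to 0. Appetite-stimulating peptides and receptors averaged -0.02, with NPY1R at 0.25 ± 0.11 (SE), and satiety peptides and receptors averaged -0.01. Releasing and neurohypophysial hormones averaged 0.04, with CHGB at 0.12 ± 0.08 (SE), leptin and insulin signalling 0.02, with IRS2 at 0.21 ± 0.14, and AMPK and mTOR energy sensing -0.02, with RPTOR at -0.15 ± 0.08. Respiratory chain genes, 49 of them measured, averaged 0.01, with COX7C at 0.47 ± 0.19 (SE). The 53 ribosomal protein genes averaged 0.01, and RPL18 alone passed adjusted over the list alone, at adjusted p = 0.0194. Glutamate synapse genes averaged 0.03, with the AMPA receptor gene GRIA2 at 0.27 ± 0.11 (SE), GABA synapse genes 0.03, with GABRG1 at 0.19 ± 0.09, and monoamine genes -0.05, with the dopamine receptor gene DRD5 at -0.39 ± 0.14. Immediate early genes averaged -0.05, with NR4A2 at 0.29 ± 0.12 (SE), thyroid and growth hormone action 0.04, with TRHDE at 0.15 ± 0.09. Inflammation genes averaged 0.04, with TNFAIP3 at 0.51 ± 0.15, complement and MHC 0.03, with SLA-DMB at -0.20 ± 0.09. Cholesterol synthesis genes averaged -0.00416, with CYP51A1 at 0.11 ± 0.07, and genes reported to escape X inactivation 0.06, with USP9X at 0.16 ± 0.08.

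Markers of the cell types and neighbouring regions that the dissected piece could hold did not separate the feed efficiency groups either. Neuron markers averaged 0.05, with ELAVL4 at 0.33 ± 0.12 (SE), astrocyte markers 0.00161, with the glutamate transporter gene SLC1A2 at 0.14 ± 0.10, and tanycyte and ependymal markers 0.03, with NES at 0.27 ± 0.10. Oligodendrocyte markers averaged -0.03, with MOG at -0.19 ± 0.10 (SE), oligodendrocyte precursors -0.04, with OLIG2 at -0.11 ± 0.08, and microglia 0.00138, with FCER1G at -0.12 ± 0.07. Endothelial markers averaged 0.01, with EMCN at 0.34 ± 0.14 (SE), pericyte markers -0.05, with MYL9 at -0.31 ± 0.19. Choroid plexus markers averaged -0.02, with STEAP1 at -0.49 ± 0.18, and lymphocyte markers -0.06, with CD3D at -0.36 ± 0.13. Red blood cell markers averaged 0.00941, with HBM at -0.19 ± 0.10 (SE), and anterior pituitary markers 0.06, with the growth hormone gene GH1 at 0.56 ± 0.38. Thalamic markers averaged 0.01, with PLEKHG1 at 0.17 ± 0.11 (SE), mammillary markers -0.07, with FOXA1 at -0.22 ± 0.11, and cortical and striatal markers -0.02, with TBR1 at 0.25 ± 0.12. Of the hypothalamic patterning factors, 16 of 19 were lower in the low group, by -0.06 on average, with NKX2-2 at -0.36 ± 0.13 (SE; adjusted p of the list = 0.562).

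Females and males differed in 8 probe sets, 5 higher and 3 lower in females. All males but only some females came from the lower run of pig identifiers, and the other females from a higher run. Sex was thus partly tied to the run, which was a term only for feed efficiency and not for sex. What the run stands for is not given, and this limit holds for every sex difference reported here. The 5 higher ones carried no gene name. The clearest, SNOWBALL_023078_st, stood at 1.99 ± 0.39 in males and 8.14 ± 0.12 in females (SD, n = 6 each), a difference of 6.14 ± 0.14 (SE; limma adjusted p = 9.10e-10). SNOWBALL_037083_st differed by 6.19 ± 0.21 (SE), SNOWBALL_028804_st by 4.13 ± 0.21, and SNOWBALL_033300_st and SNOWBALL_046594_st by 2.91 ± 0.20 and 2.92 ± 0.30. Lower in females were the unnamed SNOWBALL_035896_st, by -2.85 ± 0.20 (SE), a probe set of KDM6A, an X-linked histone demethylase gene, by -2.67 ± 0.29 (adjusted p = 0.00595), and 1 of 20 tested probe sets of GNAS, by -3.48 ± 0.44 (adjusted p = 0.0216). The other probe sets of KDM6A averaged 0.68 in the opposite direction, and those of GNAS averaged -0.05. The lower group's mean lay below the limit of 2.43 for testing and within the range of the background probe sets for GNAS and for each unnamed probe set except SNOWBALL_033300_st, so the size of these differences depends on background. The GNAS probe set passed without high feed efficiency replicate 3 or 4 and lost its call without any of the other 10 pigs, with adjusted p from 0.0545 to 0.1001. Averaged per gene, 0 genes passed, with 587 at an unadjusted p under 0.05.

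X-linked genes reported to escape X inactivation, the silencing of 1 X chromosome in females, were higher in females as a list (mean 0.25, 7 of 10 positive; camera adjusted p = 1.77e-05). The adjusted p was 0.0959 with an estimated correlation and 0.00669 with fry, and with a gene's probe sets averaged the mean was 0.14 (adjusted p = 0.00666). Adjusted over the list alone, 7 of the 10 genes passed in their brightest probe set, against 0 over all probe sets: KDM6A at 0.51 ± 0.08 (SE), USP9X at 0.41 ± 0.08, TXLNG at 0.70 ± 0.16, the translation initiation factor gene EIF2S3 at 0.52 ± 0.12, the RNA helicase gene DDX3X at 0.35 ± 0.08 and ZFX at 0.41 ± 0.11 were higher in females, and OFD1 was lower, at -0.33 ± 0.09. Apart from KDM6A and USP9X, these were chosen after their values were seen. The probe set named for the Y-linked gene EIF1AY stood at 7.35 ± 0.26 in males and 7.46 ± 0.15 in females (SD, n = 6 each), so it gave no measure of a Y-linked transcript. SRY lay below the limit for testing and XIST was named by no probe set in the annotation used here. The remaining genes of smallest unadjusted p, which did not pass, were ESYT3, IMPG2, CYP4A24, SNAP25, RSAD2 and GRHL3 on the female side and RPL19, DHX37, KLK6, MICAL3, NOG and USP42 on the male side. ESYT3 differed by 0.68 ± 0.10 (SE) and the kallikrein gene KLK6 by -0.60 ± 0.10. Without low feed efficiency replicate 3 ESYT3 passed (adjusted p = 0.0103), and without high feed efficiency replicate 3 so did CYP4A24 (adjusted p = 0.0153) and RPL19 (adjusted p = 0.0448).

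**Figure D3:**
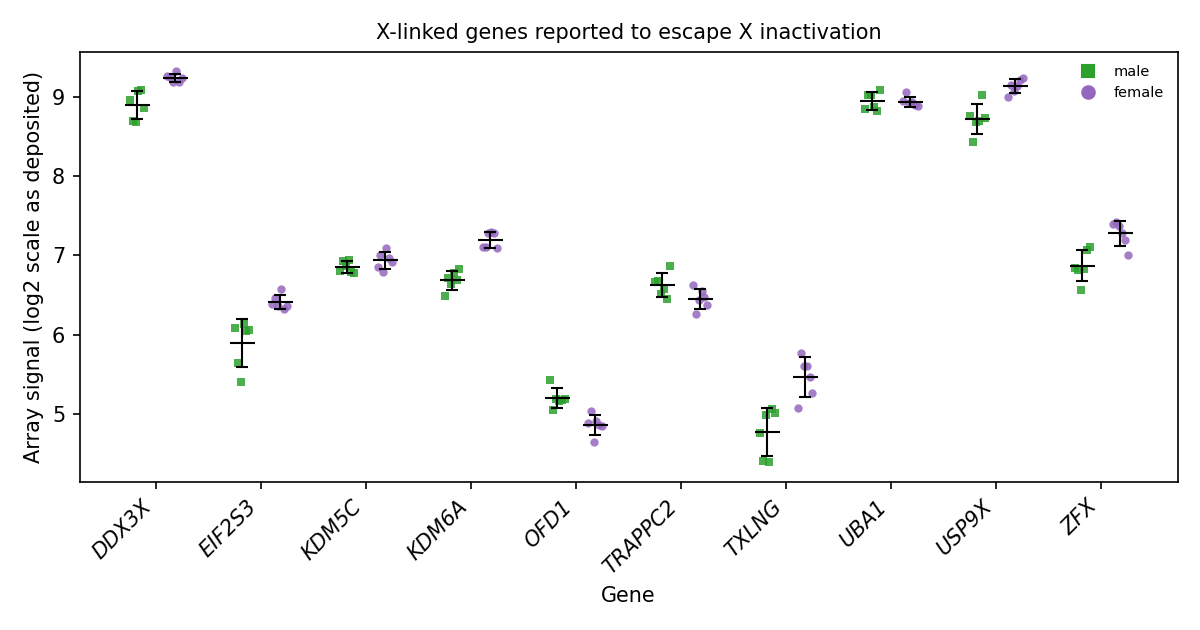
Log2 array signal (y axis) of 10 X-linked genes reported to escape X inactivation (x axis) in 6 males (green squares) and 6 females (purple circles), with black bars for mean and SD. KDM6A differed by 0.51 and DDX3X by 0.35, with females higher, while UBA1 differed by -0.00722.

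Complement and MHC genes were lower in females as a list, by -0.20 on average with 23 of 28 negative (adjusted p = 0.0283), and endothelial markers by -0.10 with 11 of 15 negative (adjusted p = 0.0318). With an estimated correlation neither was called, at adjusted p = 0.531 for both. For these lists too, sex cannot be separated fully from the run of pig identifiers. The complement and MHC list lost its call without high feed efficiency replicate 1, 5 or 6 (adjusted p = 0.135, 0.0685 and 0.0665). It also lost it without low feed efficiency replicate 1 or 5 (0.110 and 0.0825). The endothelial list lost its call without high feed efficiency replicate 3, 4 or 5 (adjusted p = 0.0943, 0.0970 and 0.0685) and without low feed efficiency replicate 2, 3, 4 or 5 (0.101, 0.0779, 0.120 and 0.0825). Of the MHC class I gene SLA-1 and the endothelial cadherin gene CDH5, chosen after their values were seen, the differences were -1.02 ± 0.30 and -0.26 ± 0.11 (SE), and neither passed. The other probe set of SLA-1 differed by 0.09, in the opposite direction.

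Within males, 3 probe sets passed between low and high feed efficiency, each at limma adjusted p = 0.0475. At an unadjusted p under 0.05 there were 3156, against 1790 expected by chance. This count was 2233 without low feed efficiency replicate 2 and 3908 without high feed efficiency replicate 1. It was not set against other splits of the pigs, so no excess can be read from it. A probe set of PNPLA8, a mitochondrial and peroxisomal phospholipase gene, stood at 3.94 ± 0.25 in high and 5.73 ± 0.17 in low males (SD, n = 3 each), and one of HINT3 at 1.76 ± 0.23 and 3.15 ± 0.23 (SD, n = 3 each). One of SLA2, an adaptor protein gene of lymphocyte signalling, stood at 4.30 ± 0.60 in high and 1.36 ± 0.26 in low males (SD, n = 3 each). The other probe set of each gene differed by 0.27 for PNPLA8, 0.19 for HINT3 and 0.13 for SLA2, which for SLA2 was the opposite direction. The SLA2 signal in low males and the HINT3 signal in high males lay below the limit of 2.43 for testing and within the range of the background probe sets, so the size of these differences depends on background. RBM34, THRAP3 and SYT4 followed on the higher side and SRSF9, CIB1, ARID1B and ARRDC1 on the lower side without passing, RBM34 at 1.04 ± 0.13 (SE; adjusted p = 0.0788). With a fit of the 6 males alone, or with array weights, 0 probe sets passed, and without any 1 of the 12 pigs 0 or 1 passed, which without high feed efficiency replicate 3 was none of the 3. For PNPLA8 the adjusted p lay between 0.0559 and 0.264 without each pig except high feed efficiency replicate 4, without which it passed. HINT3 lost its call without any 1 pig, and SLA2 kept it without high feed efficiency replicate 1 or low feed efficiency replicate 5. In females the same probe sets differed by 0.02 for PNPLA8, -0.51 for HINT3 and 0.79 for SLA2.

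Within females, limma called 0 probe sets, with 1497 at an unadjusted p under 0.05 and a smallest adjusted p of 0.359. Leading without passing were SLC9A3R1 at 1.65 ± 0.28 (SE), COL19A1 at 0.51 ± 0.09, ZNF711, COG7 and BRDT on the higher side and the peptide transporter gene TAP1 at -0.81 ± 0.15, KLHL14 at -1.03 ± 0.20, NKX2-2, TEAD3 and GXYLT1 on the lower side. The interaction of feed efficiency and sex also had 0 calls, with 2174 at an unadjusted p under 0.05 and a smallest adjusted p of 0.152, reached by HINT3 at -1.90 ± 0.23 (SE) and SLA2 at 3.72 ± 0.47. CIB1, MIR30E, KCNK5, LOC396781, PNPLA8, PTPN4, SYT4 and THRAP3 were the others named and did not pass.

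In 2 lists the feed efficiency difference differed between the sexes by camera at the preset correlation, and neither was called with an estimated correlation (adjusted p = 0.820 for oligodendrocyte and 0.277 for choroid plexus markers) or with fry (0.615 and 0.0558). Oligodendrocyte markers, the genes of the myelin-forming cells, had a mean interaction of -0.29 with 13 of 14 negative (adjusted p = 0.00114), and choroid plexus markers, from the tissue that secretes cerebrospinal fluid, a mean of 0.42 with 10 of 13 positive (adjusted p = 0.0146). In males the choroid plexus mean was 4.85 ± 0.08 in the high and 4.62 ± 0.05 in the low group, and in females 4.62 ± 0.02 and 4.81 ± 0.11 (SD, n = 3 each). TTR, the transthyretin gene, chosen after the list was seen, had an interaction of 1.87 ± 0.63 (SE) and did not pass (adjusted p = 0.779). The oligodendrocyte list lost its call without low feed efficiency replicate 3 or 4 (means -0.23 and -0.19, adjusted p = 0.0527 and 0.0811), and the choroid plexus list without high feed efficiency replicate 1 or 4 (0.116 and 0.0587), without low feed efficiency replicate 3 (0.0527) and with a gene's probe sets averaged (0.0850).

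**Figure D4:**
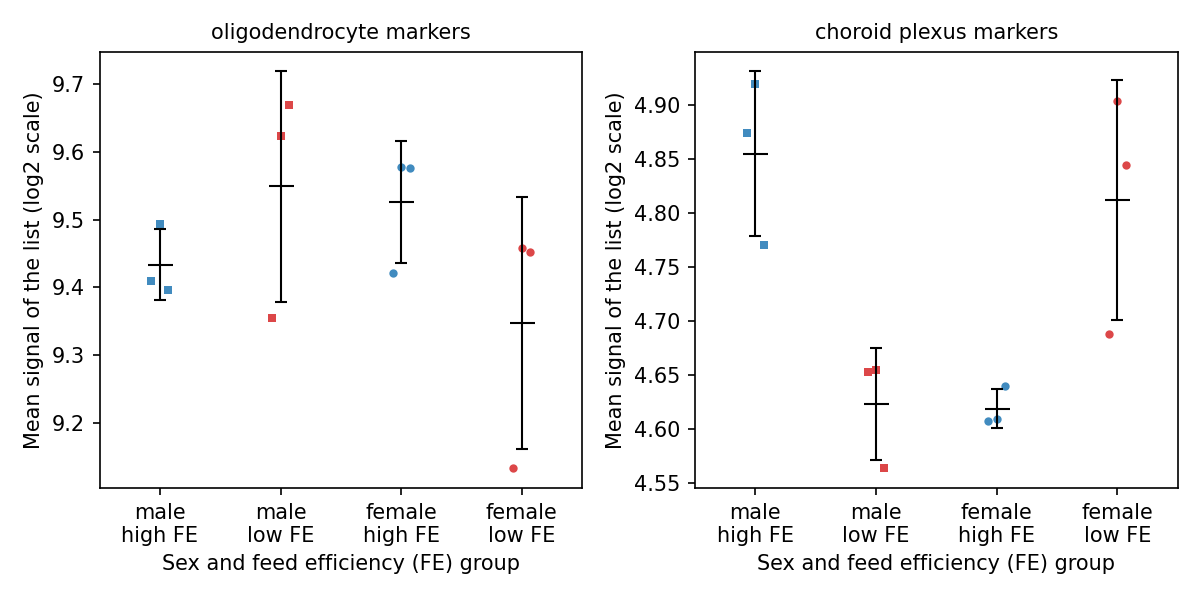
Mean log2 signal (y axis) of 14 oligodendrocyte and 13 choroid plexus marker genes in each pig, by sex and feed efficiency group (x axis); black bars give the mean and SD of 3 pigs, and the y axes do not start at 0. Choroid plexus means were 4.85 and 4.62 in high and low males and 4.62 and 4.81 in high and low females.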

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

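Of the tests in this part, those on background signal, on white matter and a shift of whole arrays as the whole cause and on the interaction of the 3 male probe sets, and the counts of splits for feed efficiency, its interaction with sex and the females, were written down after their result was seen; the genes of the clock tests were chosen after DBP and NR1D1 had been seen.

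The mean interaction of the oligodendrocyte markers, -0.29, and that of the choroid plexus markers, 0.42, were picked out because the feed efficiency difference in females differed from that in males. An exact permutation of sex within the feed efficiency groups gave p = 0.095 for the oligodendrocyte mean, so the spread between pigs of genes that vary together is a possible explanation there. For the choroid plexus mean the exact permutation p was 0.005, the smallest that 400 permutations can give. This p is not corrected for the 37 lists from which the pattern was picked. The permutation also assumes no sex difference of any kind within a feed efficiency group. With an estimated correlation or fry the list was not called, so the permutation cannot decide whether that spread explains the choroid plexus interaction. Choroid plexus tissue attached to the dissected piece, in amounts that differed between the 4 groups, may account for it and stays open: TTR, an abundant choroid plexus transcript and a member of the list, had an interaction of 1.87 (adjusted p = 0.779), above the list's 0.42, and of other members, chosen after their values were seen, SLC13A4 and FOLR1 had 0.67 ± 0.22 and 0.39 ± 0.17 and KL, AQP1 and KCNJ13 0.19 ± 0.21, 0.20 ± 0.28 and 0.31 ± 0.32 (SE). In all, 10 of the list's 13 members had a positive and 3 a negative interaction, and its estimated inter-gene correlation was -0.026. The list's group means, 4.62 to 4.85, lay within the background probe sets' range of 1.30 to 7.49. A difference between the sexes in how the choroid plexus relates to feed efficiency remains open and untested.

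The 3 probe sets that passed within males may reflect the single probe set, such as a sequence variant under the probes or its annotation. The other probe sets of the same genes had a median of 0.139 of the called difference, counting only the 3 other probe sets that exist. Whether males and females differ here cannot be told apart from spread, since the smallest adjusted p of the interaction was 0.152 after correction over all probe sets. The 6 males make 10 splits, too few for a share under 0.05, with 3 probe sets in the real one and at most 0 in another.

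The lower signal of clock output genes in the low group averaged -0.18 ± 0.06 (SE) over 9 genes, 8 of them negative, but these genes were chosen after DBP and NR1D1 had been seen, and the list of 16 clock genes fixed before averaged -0.08 and was not called (adjusted p = 0.317). A shift of clock phase or of the time of sampling could produce it and would raise the opposite-phase genes, but the 3 of these that were tested went both ways, with NPAS2 at -0.12, CLOCK at 0.12 and NFIL3 at 0.25, and their mean of 0.0835 ± 0.0758 (SE; exact permutation p = 0.32) decides nothing. With the oligodendrocyte mean as a term the clock difference was -0.177 ± 0.061 (SE), against -0.176 without it. It lay -2.88 standard errors from 0, which is no independent test, since the genes were chosen after DBP and NR1D1 had been seen. Oligodendrocyte markers differed by only -0.03 between the groups, so the term had little to remove. With these markers as the measure of white matter, the clock difference thus did not shrink. The test of white matter written down before its result was seen was undecided, so a part of white matter in the difference stays open. Probe sets at an unadjusted p under 0.05 went from 2201 to 2402 with the term, which says nothing about the clock genes. With array medians set equal the clock difference was -0.154 ± 0.0634 (SE), or -2.44 standard errors from 0, with the same limit from the choice of genes. Most of the difference stayed, which argues against a shift of whole arrays as the whole cause. Background probe sets shifted by a median of -0.0184 ± 0.0524 (SE), too uncertain to exclude a part in background signal, and feed efficiency itself also remains open.

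For feed efficiency, the interaction and the females the real split gave 0 probe sets, so all splits, 100 of 100, 100 of 100 and 10 of 10, reached it by construction and say nothing about chance. The highest of the other splits gave 1, 2 and 1. For sex, 1 of 100 splits, the real one, gave 8, and the highest other gave 1, so chance is an unlikely source of this count. Only 100 of the 200 possible splits were run, and the count does not speak for each of the 8 probe sets.

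Single pigs stood apart from the other 5 of their group in 22 of 306 groups of 6 values, where chance gives about 1 in 20, or 15.3. Among list means, high feed efficiency replicate 4 had an interferon mean of 6.49, above 6.17 to 6.20 in the others, replicate 1 a meningeal fibroblast mean of 7.43, replicate 3 an immediate early gene mean of 5.28, and replicate 6 a thalamic mean of 7.13 and an astrocyte mean of 9.84. In the high group, replicate 1 was highest for COL3A1 at 6.08, COL1A1 at 9.68 and MYL9 at 6.23, replicate 2 was lowest for DNAJC3 at 7.13, FOXA1 at 3.67 and TBR1 at 4.89, and replicate 3 was lowest for TRHDE at 5.22 and SLC1A2 at 9.49. Replicate 4 was highest for VEGFC at 3.03, replicate 5 highest for NPY at 5.67 and replicate 6 lowest for PMCH at 7.23. In the low group, replicate 6 was highest for HSPA5 at 10.48, replicate 3 lowest for GABRG1 at 9.40 and replicate 4 lowest for MYL9 at 4.69. Among the males, low feed efficiency replicate 2 was highest for ABCB1 at 5.48, and among the females, high feed efficiency replicate 4 was highest for GNAS at 4.43 and replicate 5 for USP42 at 4.13.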

How the results depend on the processing

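The count of 0 probe sets for feed efficiency held under every alternative run except without low feed efficiency replicate 2, with a range of 0 to 1 when 1 pig was left out; the interaction and the females stayed at 0 under all alternatives, 0 to 0 without single pigs. The 8 probe sets of the sex comparison became 2 with the dimmest 50 percent left out, 5 in unmoderated linear models and 0 with a gene's probe sets averaged, since most of the 8 have no gene name, and ranged from 7 to 10 without single pigs. The 3 probe sets within males became 0 with no filter, with array weights, in unmoderated models and in the 6 males alone. They became 1 with the dimmest 50 percent left out, 2 with trend and robust settings, and 0 to 1 without single pigs. With a gene's probe sets averaged 2 genes passed in limma, PNPLA8 and HINT3, at 1.03 and 0.79 (adjusted p = 0.0246), and SLA2 did not (adjusted p = 0.115). Each average includes the called probe set itself, so it gives no independent evidence for the gene. The share of variance ranged from 11.2% to 13.01% without single pigs. With 1 pig fewer any split holds a larger share, so this range shows no rise over the 10.9% of all pigs. For feed efficiency 0 lists passed, with a range of 0 to 1 without single pigs. The 3 lists of the sex comparison became 0 with an estimated correlation and 1 with fry, and 2 to 5 without single pigs. The 2 lists of the interaction became 0 with an estimated correlation or fry, 1 with a gene's probe sets averaged, and 0 to 3 without single pigs. The cause of these changes was not tested unless named. In single genes, the other probe sets of KDM6A averaged 0.678 against -2.67, and those of SLA2 0.129 against -2.93. Quantile normalization kept the direction and call of all 254 gene differences examined. The replicate numbers were given in accession order, and the labels state no pairing. Same-numbered pigs did share their sex, and the low pig's identifier always lay the same distance above the high pig's. A pairing in the design can therefore not be excluded. With the number as a replicate block in place of sex, chosen after the data had been seen, 0 probe sets passed for feed efficiency, as without it. Deviations of same-numbered pigs from the means of the 4 groups correlated at -0.00281 to 0.0880, none of 6 pairs over 0.1, and 4 of 12 pigs correlated best with the pig of their number. The second principal component did go together between same-numbered pigs (correlation 0.948, and 0.945 after the means of the 4 groups were removed). This sign of a pairing was not followed further. The gene lists were not tested with the block, and the share of variance and the other exact permutations were not run within pairs. Signals near the background range of 1.30 to 7.49 limit what small differences in dim genes can show. This range pools all G and C contents and covers most signals of every array. It includes the group means of DBP, NR1D1, PER3, TEAD3 and the choroid plexus list.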

Other observations

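Among lymphocyte markers, CD4 and CD2 passed between the sexes adjusted over the list alone (limma adjusted p = 0.0335 and 0.0398) and not over all probe sets. CD4, a T cell and macrophage surface gene, stood at 7.39 ± 0.47 in males and 6.53 ± 0.38 in females, and CD2, a T and NK cell adhesion gene, at 7.12 ± 0.11 and 7.51 ± 0.28 (SD, n = 6 each). CD2 was the 1 member of 11 that was higher in females; the list averaged -0.13, with 10 of 11 lower in females, and was not called (camera adjusted p = 0.143, and 0.531 with an estimated correlation). The other probe sets of CD4 and CD2 averaged -0.07 and -0.08. The interferon-induced gene RSAD2 differed by 0.63 ± 0.13 (SE), higher in females, and passed adjusted over its list alone at adjusted p = 0.0113.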
